A study of Mus musculus with 8 samples.

How the data were processed

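Whole kidneys of 8 mice were sequenced, 4 wild-type (WT) and 4 Six2-Cre, floxed Cox10 conditional knockout (cKO). Per the labels, kidneys were flash frozen, RNA was isolated with a column kit, and stranded libraries of polyadenylated RNA were sequenced on an Illumina instrument. The submitters name STAR and RSEM and the mouse genome build mm10, and the versions of these tools, the annotation release and the strand setting are not given in the sources used here. The deposited files hold RSEM expected counts, which the authors estimated per Ensembl gene and did not scale, 1 file per library with 47643 genes. A gene that shares reads with another can hold a fractional expected count. Of the identifiers, 47224 were matched to a gene symbol and position in the GENCODE annotation of the same build. The column totals, 9454830 to 15838026, are the depths per library, and counting error and the floor of 3 counts cover sampling only. The floor was used over a group in which every library held 0.

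Expected counts were rounded to whole numbers. Genes were kept by filterByExpr on genotype, which left 13829, and scaled by the trimmed mean of M values (TMM). CPM values use TMM-scaled library sizes. Genotypes were compared with the edgeR quasi-likelihood test (glmQLFit and glmQLFTest, robust), a two-sided test, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The log2 fold change is cKO over WT, and SD values are over the 4 libraries of a group. Cox10 was also tested by an exact two-sided permutation of log2 CPM over the 35 splits of the 8 libraries. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.

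The comparisons, the alternatives and 52 gene lists of the respiratory chain, stress responses, metabolism, nephron segments, injury, other cell types, immune response, endocrine function and sex were fixed before the data were examined. Lists with at least 5 tested members, 48 of them, were tested with camera on voom log2 CPM with a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation, camera on ranks and fry were run beside it. Members called rose or fell passed the edgeR adjusted p over all tested genes, and counts adjusted over the list alone use only the members' p values. A list was written from general knowledge of the tissue and not from these samples.

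Genes are named by a rule fixed in advance. It takes Cox10, the 10 largest rises and 10 largest falls among called genes with a mean CPM of at least 1, groups that do not overlap and a symbol that is not a predicted or clone name, and the 3 most abundant called genes in each direction that changed at least 2-fold. It also takes up to 4 members of each list with the smallest adjusted p among those called, or the 2 most abundant where 0 passed, and lets the sex-linked and sample make-up genes be named in any library. Genes outside the rule are named as chosen after their values were seen.

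Alternatives were RLE, upper quartile and library size scaling, leaving out mitochondrially encoded genes or the 20 most abundant genes before scaling, no count filter and a filter of 1 CPM in 4 libraries, DESeq2 and limma-voom, other thresholds, an age term, a replicate block, a sex term, leaving out each library in turn and leaving out the 2.5-month pair. Libraries with at least 10 counts of Y-linked genes were taken as bearing a Y chromosome. Contrasts within each sex from a 4-group fit, leaving out the pair with the later sample numbers, a term for the number run and the permutation of list means were added after seeing the data. Replicate numbers were not taken as pairs, though replicate 2 shares an age and replicate 4 the later sample numbers in both groups. Same-number correlations between WT and cKO residuals were -0.08, 0.28, 0.12 and 0.00, against -0.28 to 0.20 for different numbers. The block is therefore given only as an alternative. An alternative on TPM or FPKM was left out, since the values analysed here are counts.

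The steps were tested on simulated data made from the same counts. Of 100 genes changed 2-fold 18% were called, of 100 changed 4-fold 86% were called, 6 of 110 calls were false (5.45%), and with nothing changed there were 0 calls. Only these genes among 13829 were changed, and the adjusted threshold depends on how many genes change. The shares called are therefore not those of the real comparison, in which 2310 genes were called. Of 47 lists tested in the simulation, only the list that had been shifted was called. Each gene was drawn independently, so the simulation does not show how the list test behaves when members are correlated. Some members of the gene lists count in the totals and are not reported here by name.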

Results

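The data are RNA sequencing counts from 8 mouse kidneys. 4 kidneys came from wild-type mice (WT) and 4 from conditional knockout mice (cKO) in which Six2-Cre recombined a floxed Cox10 gene. Cox10 encodes heme A farnesyltransferase, an enzyme needed to build cytochrome c oxidase, which is complex IV of the mitochondrial respiratory chain. Six2-Cre is active in nephron progenitors, so the epithelium of the nephron that descends from them carries the deletion, while the collecting duct, vessels and blood cells have another origin. The labels give an age of 3 months for replicates 1, 3 and 4 of each group and 2.5 months for replicate 2 of each group. The deposited values summed to 12922517, 9731334, 12033758 and 15838026 counts in WT 1 to WT 4 and to 14837448, 9454830, 13186808 and 14136365 in cKO 1 to cKO 4. Each library held at least 1 count for 16176 to 18316 genes. Among pairs of libraries within a genotype the closest, WT 3 and WT 4, still differed with a chi-square of 17.4 per gene, where sampling noise alone gives about 1, so no library was a copy of another of its genotype.

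The labels do not give the sex of the animals, and reads from the Y chromosome separated the libraries into animals with and without them. WT 2, WT 3, WT 4 and cKO 3 held 829, 1487, 1707 and 848 counts of Y-linked genes, and WT 1, cKO 1, cKO 2 and cKO 4 held 0. Xist, the RNA that silences an X chromosome in females, had 104, 244, 330 and 101 counts in WT 1, cKO 1, cKO 2 and cKO 4, and at most 3 in each of the others. Thus 1 of 4 WT and 3 of 4 cKO libraries lacked Y-linked reads. A sex term and contrasts within each sex therefore stand beside the pooled values. On the 1000 most variable genes, the first principal component held 66% of the variance and separated the genotypes, and WT 1 lay apart from the rest on the second, which held 11.2%.

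**Figure D1:**
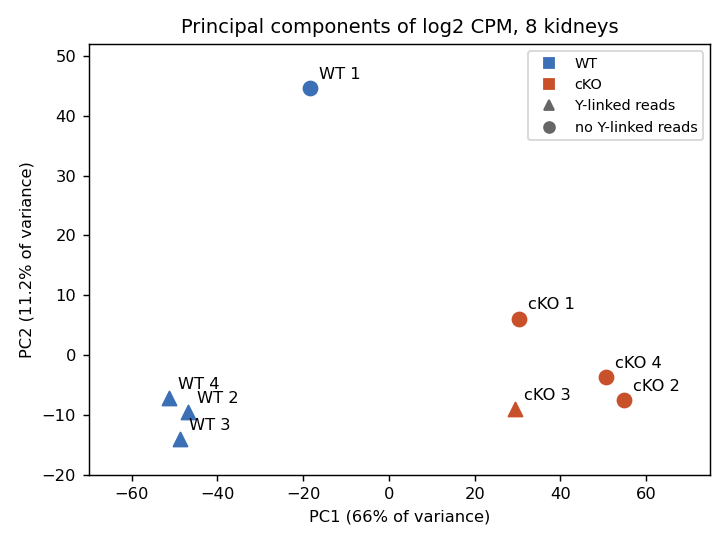
Principal components 1 and 2 of log2 CPM over the 1000 most variable genes, 1 point per library, coloured by genotype and shaped by the presence of Y-linked reads. The 4 WT libraries lie below 0 and the 4 cKO libraries above 0 on component 1 (66% of variance), and WT 1 lies at 44.69 on component 2 (11.2%).

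The first comparison asked whether the targeted gene itself was lower in cKO kidneys. Cox10 (ENSMUSG00000042148, mm10 chromosome 11, 63962627 to 64079468, 7 exons in the annotation) had 21 ± 2.47 scaled counts (CPM; SD, n = 4) in WT and 18.4 ± 5.12 (SD, n = 4) in cKO kidneys. These values rested on 285, 171, 235 and 316 counts in WT 1 to WT 4 and 319, 100, 292 and 342 in cKO 1 to cKO 4. The cKO to WT ratio was 0.876, and the log2 fold change was -0.19 with a 95% interval from -0.72 to 0.34. The difference was larger than the SD in WT and smaller than that in cKO, where cKO 2 held 10.9 CPM and the others 19.5 to 22.3. It did not pass, with an edgeR adjusted p of 0.619 and an exact two-sided permutation p of 0.514 over 35 splits, whose smallest possible value is 0.0286. With a sex term the log2 fold change was -0.20, within the libraries without Y-linked reads it was -0.48, and within those with them it was 0.07. The labels do not say which part of Cox10 is floxed, and cells outside the nephron keep the gene, so a total over the whole gene cannot check the labels.

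The second comparison asked how the kidney transcriptome of the cKO mice differed from WT. Of 13829 genes tested with edgeR, 2310 (16.7%) differed at an adjusted p under 0.05, 1323 higher and 987 lower in cKO, and 1900 of them changed by at least 2-fold. All 4 cKO libraries lay above or below all 4 WT libraries for 2005 of the 2310, and for 22.6% of all tested genes, where chance gives 2.86%. With a sex term 941 genes differed, 715 higher and 226 lower, of which 931 were among the 2310. Within the libraries without Y-linked reads 120 genes differed and within those with Y-linked reads 480 did, each contrast resting on a single library on 1 side. The direction was the same in both of these contrasts for 2277 of the 2310 genes (98.6%), a share that their call on the same libraries in part fixes, and for 57.9% of the other tested genes. Leaving out WT 3, WT 4 or cKO 4 took the count to 1438, 1288 or 1155, and leaving out WT 4 and cKO 4 together, whose sample numbers in the file headers form a later run, took it to 568. With all libraries kept and a term for the number run 1988 genes differed, of which 1957 were among the 2310. Scaling by library size alone moved the median of all genes by 0.159 on the log2 scale and gave 1866 higher and 550 lower.

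The naming rule took the 10 largest rises and the 10 largest falls among called genes. Among genes with no count in any WT library, the interleukin Il1f6 was at least 133-fold higher in cKO (floor of 3 counts over the WT group), the chemokines Cxcl17 and Ccl20 at least 66.4-fold and 48.6-fold, the acute-phase gene Saa1 at least 46.6-fold and Arhgap36 at least 66.1-fold. The small proline-rich gene Sprr2f rose from 0.0366 ± 0.0428 to 27.3 ± 24.6 CPM on 2 and 1484 counts, the matrix protease Mmp10 from 0 to 4.14 ± 3.70, and the BMP antagonist Grem1 from 0.126 ± 0.145 to 49.3 ± 32.7. Of the falls, the tenascin family gene Tnn went from 11.0 ± 5.15 to 0.0494 ± 0.0332 CPM on 493 and 3 counts, and the homeobox gene Rhox6 from 3.90 ± 1.46 to 0.0356 ± 0.0711. The aldo-keto reductase Akr1c14 fell from 514 ± 308 to 11.8 ± 8.63 CPM, the atrial natriuretic peptide-converting enzyme Corin from 4.95 ± 1.94 to 0.153 ± 0.0438, and the potassium channel Kcnt1 from 7.51 ± 3.35 to 0.161 ± 0.163 (SD, n = 4 throughout). The edgeR adjusted p of these genes ranged up to 0.00259, and for each of them all 4 cKO libraries lay on the same side of all 4 WT libraries.

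**Figure D2:**
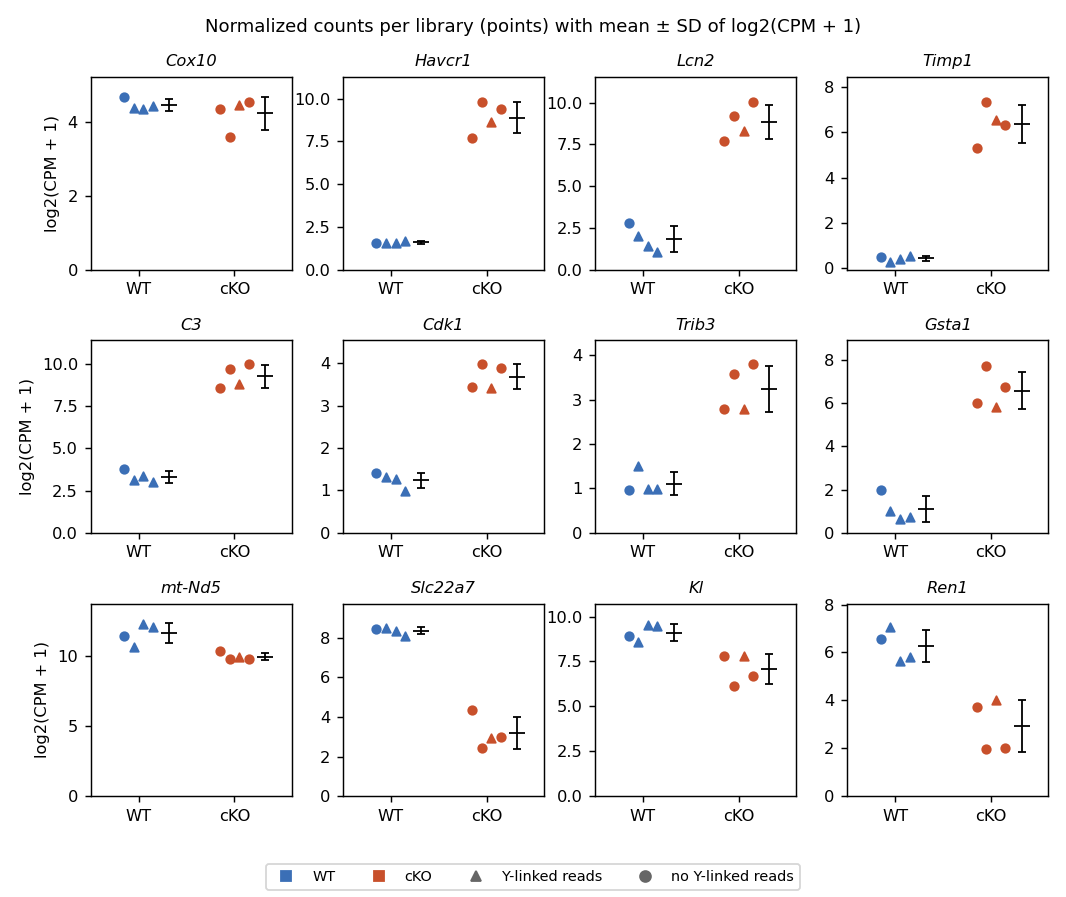
Normalised counts of 12 genes as log2(CPM + 1), 1 point per library, with the mean and SD of each group beside the points (n = 4) and point shape giving the presence of Y-linked reads. Cox10 overlaps between genotypes, Havcr1, Lcn2, Timp1, C3, Cdk1, Trib3 and Gsta1 lie higher in all 4 cKO libraries, and mt-Nd5, Slc22a7, Kl and Ren1 lie lower in all 4.

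Gene lists fixed before the data were examined were tested with camera. Of 48 lists with at least 5 tested members, 26 passed an adjusted p under 0.05, 16 up and 10 down in cKO. With a correlation estimated for each list 3 passed, namely cell cycle, cytokines and NF-kB targets, and NRF2 targets. Other splits of the same 8 libraries gave up to 33 lists with the preset correlation and 0 with an estimated one. Those that reached 26 held unequal numbers of the genotypes and so kept part of the genotype difference. Splits with equal numbers gave 3 to 18 lists. The number of lists alone is therefore not taken as evidence of a difference, and the splits do not decide. The split by Y-linked reads gave 27 lists, and the fit of genotype with a sex term gave 25. An exact permutation test of each list's mean, chosen after the data were seen, gave its smallest possible p of 0.0286 for 21 of the 26, and the other 5 are given with their value. These permutation p values are not adjusted over the lists, and 22 of the 48 tested lists reached the smallest one. Of the 26 lists, fry did not call NAD synthesis, interferon response, adipocyte and male-biased genes. Without the 2.5-month pair mitochondrial chaperones and proteases, endocrine and male-biased genes lost their call, and without WT 4 and cKO 4 the first 2 of these did. Endocrine genes also lost it on ranks and with no count filter, nucleic acid sensing on ranks and with the replicate block, and mitochondrial chaperones and proteases with that block. T and NK cell genes passed by fry, and they and the loop of Henle passed on ranks, with the replicate block, the age term, no count filter or without WT 4 and cKO 4, as did fatty acid oxidation in each of these but the block. Without WT 4 and cKO 4 the endothelial list passed too, and with no count filter the red blood cell list did. No list past the threshold changed the sign of its median under any scaling. Of 172 genes named by a rule fixed in advance, 56 lost their call when 1 library was left out (2, 28, 39 and 47 without WT 1 to WT 4, and 13, 37, 26 and 50 without cKO 1 to cKO 4), with a highest edgeR adjusted p between 0.0508 and 0.157. These are called marginal where they are first named. A sex term ended the call of 57 of the 172, and leaving out WT 4 and cKO 4 together ended that of 82. Of the genes named here that are not marginal, a sex term ended the calls of Ppargc1a, Pcx, Afmid, Slc5a8, Aqp2, Ehd3 and Upk1b, at log2 fold changes of -1.29, -0.96, -1.35, -1.20, 1.71, -0.99 and 1.66 against -1.35, -1.35, -1.56, -1.98, 1.98, -1.01 and 1.94 without it. Without the 2.5-month pair Pcx, Cyp51, Pecr and Slc5a8 lost theirs. Leaving out WT 4 and cKO 4 ended those of Slc5a8, Ctsd, Ppargc1a, Pck2, Slc38a3, Pcx, Fdps, Cyp51, Mthfd2, Afmid, Pecr, Cldn16, Nes, Wnt4, Lck, Agtr1a, Upk3a, Upk1b, Hbb-bt, mt-Nd5, Kl and Aqp2. Agt, Ccnd1, Crot, Cyp4b1, Ifi44, Krt14, Me1, Mthfd1l, Ndrg1, Pdgfra, Phgdh, Psat1, Pth1r and Slc37a4 were chosen after their values were seen and not run with a library left out.

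Tubular injury genes rose almost throughout, with 21 of 24 higher and a median log2 fold change of 2.39 (camera adjusted p = 3e-17; adjusted p = 0.15 with an estimated correlation). Havcr1 (kidney injury molecule 1, ENSMUSG00000040405, chromosome 11, 46735080 to 46779578) rose from 2.00 ± 0.134 to 549 ± 306 CPM, a log2 fold change of 8.09 (SE 0.52, edgeR adjusted p = 1.85e-05). Lcn2, an iron-binding protein shed by damaged tubules, rose from 2.97 ± 2.21 to 543 ± 375 CPM and the adhesion molecule Vcam1 from 6.79 ± 2.60 to 80.8 ± 9.08. Spp1, which encodes osteopontin, went from 852 ± 731 to 16470 ± 6212 CPM. Fibroblast and extracellular matrix genes rose in 25 of 26 cases with a median of 1.78 (camera adjusted p = 5.4e-17; adjusted p = 0.13 with an estimated correlation), and the remaining member, the fibroblast receptor Pdgfra, fell by 0.91 on the log2 scale. The protease inhibitor Timp1 rose from 0.360 ± 0.103 to 91.7 ± 49.5 CPM, collagen Col3a1 from 24.3 ± 6.07 to 192 ± 57.4, fibronectin Fn1 from 19.5 ± 5.74 to 124 ± 25.8 and Sparc from 138 ± 41.1 to 879 ± 255. Of 14 pericyte, mesangial and smooth muscle genes 9 rose, median 1.00 (camera adjusted p = 4.9e-05; adjusted p = 0.24 with an estimated correlation), among them the contractile genes Acta2, from 55.7 ± 15.2 to 191 ± 38.3 CPM, and Tagln, from 49.9 ± 25.6 to 334 ± 167. When adjusted over the list alone, 22, 25 and 9 members of these lists rose. With a sex term 20, 20 and 8 rose, and the medians were 2.51, 1.96 and 1.17 within the libraries without Y-linked reads and 2.09, 1.90 and 1.03 within those with them.

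Macrophage and monocyte genes rose in 20 of 21 cases, with a median log2 fold change of 2.21 (camera adjusted p = 6.2e-13; adjusted p = 0.15 with an estimated correlation). The lysosomal protein Cd68 rose from 2.24 ± 1.11 to 15.0 ± 6.06 CPM, the mannose receptor Mrc1 from 1.97 ± 0.535 to 10.7 ± 4.47 and the integrin Itgam from 0.783 ± 0.437 to 5.11 ± 0.807. Antigen presentation genes rose in 13 of 17 cases, median 1.58 (camera adjusted p = 5.5e-11; adjusted p = 0.13 with an estimated correlation), with the class II gene H2-Ab1 going from 75.7 ± 20.8 to 368 ± 38.4 CPM. Cytokines and NF-kB targets rose in 17 of 22 cases, median 1.68 (camera adjusted p = 2.4e-11; adjusted p = 0.012 with an estimated correlation). The monocyte chemokine Ccl2 rose from 0.333 ± 0.326 to 8.24 ± 3.68 CPM, the adhesion molecule Icam1 from 13.0 ± 1.66 to 40.7 ± 2.48 and the NF-kB subunit Relb from 3.49 ± 0.952 to 16 ± 3.52. Complement genes rose in 9 of 13 cases, median 1.06 (camera adjusted p = 3.2e-05; adjusted p = 0.081 with an estimated correlation). C3 went from 9.23 ± 2.64 to 672 ± 305 CPM and Cfi from 3.69 ± 1.96 to 72.8 ± 14.5. The complement inhibitor Cd55 fell from 24.7 ± 7.21 to 8.33 ± 1.78. Of these 4 lists, 20, 14, 18 and 10 members rose adjusted over the list alone, and with a sex term 16, 11, 14 and 6 did. Within the libraries without Y-linked reads the medians were 1.22, 1.02, 1.45 and 1.05, and within those with them 2.72, 1.62, 1.87 and 1.21.

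Interferon response genes rose in 6 of 26 cases and fell in 1 (Ifi44), with a median of 0.62 (camera adjusted p = 0.0042; adjusted p = 0.59 with an estimated correlation; exact permutation p = 0.0857). Nucleic acid sensing genes rose in 2 of 8 cases, median 0.31 (camera adjusted p = 0.048; adjusted p = 0.24 with an estimated correlation), and without cKO 3 the camera adjusted p was 0.066. The members that rose were Tmem173, which encodes the adaptor STING, from 2.70 ± 0.771 to 16.9 ± 3.97 CPM, and the marginal Ifi204. Adjusted over the list alone, 8 interferon genes rose and 2 fell, and 3 sensing genes rose, while with a sex term 1 rose in each list. The medians of the interferon and sensing lists were 0.11 and 0.36 within the libraries without Y-linked reads and 1.28 and 0.43 within those with them. Of 5 tested T and NK cell genes 1 rose, the kinase Lck, also adjusted over the list alone and with a sex term (camera adjusted p = 0.053, and 0.037, 0.05 and 0.018 without WT 1, cKO 2 or cKO 4). Of the B and plasma cell list only Cd79b and Jchain were expressed highly enough to test and neither passed, and of the neutrophil and adrenal cortex lists 0 members were tested.

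Cell cycle genes rose in 17 of 22 cases with a median log2 fold change of 2.12, and 1 fell, Ccnd1, which encodes cyclin D1 (camera adjusted p = 2.4e-11; adjusted p = 0.013 with an estimated correlation). The mitotic kinase Cdk1 rose from 1.37 ± 0.287 to 12 ± 2.63 CPM, the replication helicase subunit Mcm5 from 3.61 ± 0.210 to 12.5 ± 0.674 and Birc5 from 1.02 ± 0.286 to 6.12 ± 0.466. Of 19 p53 targets 9 rose, median 0.76 (camera adjusted p = 0.00031; adjusted p = 0.15 with an estimated correlation). Cdkn1a, which arrests the cell cycle, went from 4.95 ± 3.01 to 50.9 ± 22.3 CPM and Phlda3 from 5.91 ± 2.04 to 34.9 ± 10.8. NRF2 targets of the oxidative stress response rose in 11 of 18 cases, median 1.21, and the NADPH-forming malic enzyme Me1 fell (camera adjusted p = 1.5e-05; adjusted p = 0.037 with an estimated correlation). The quinone reductase Nqo1 rose from 81.3 ± 20.5 to 362 ± 92.8 CPM, and the glutathione transferase Gsta1 from 1.30 ± 1.11 to 109 ± 71.3, a value shared in part with related genes. Targets of ATF4 in the integrated stress response rose in 17 of 33 cases, median 1.02, and the serine hydroxymethyltransferase Shmt2 fell, a marginal call (camera adjusted p = 1.6e-06; adjusted p = 0.24 with an estimated correlation). Trib3 rose from 1.18 ± 0.435 to 8.91 ± 3.51 CPM, Atf5 from 12.6 ± 2.25 to 51.5 ± 19.3 and the amino acid transporter Slc7a5 from 2.59 ± 0.425 to 10.8 ± 4.08. When adjusted over the list alone, 19, 10, 11 and 20 members of these 4 lists rose, and with a sex term 14, 8, 10 and 8 did. The medians within the libraries without Y-linked reads were 1.96, 0.82, 0.86 and 0.77, and within those with them 2.28, 0.77, 1.44 and 0.72.

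**Figure D3:**
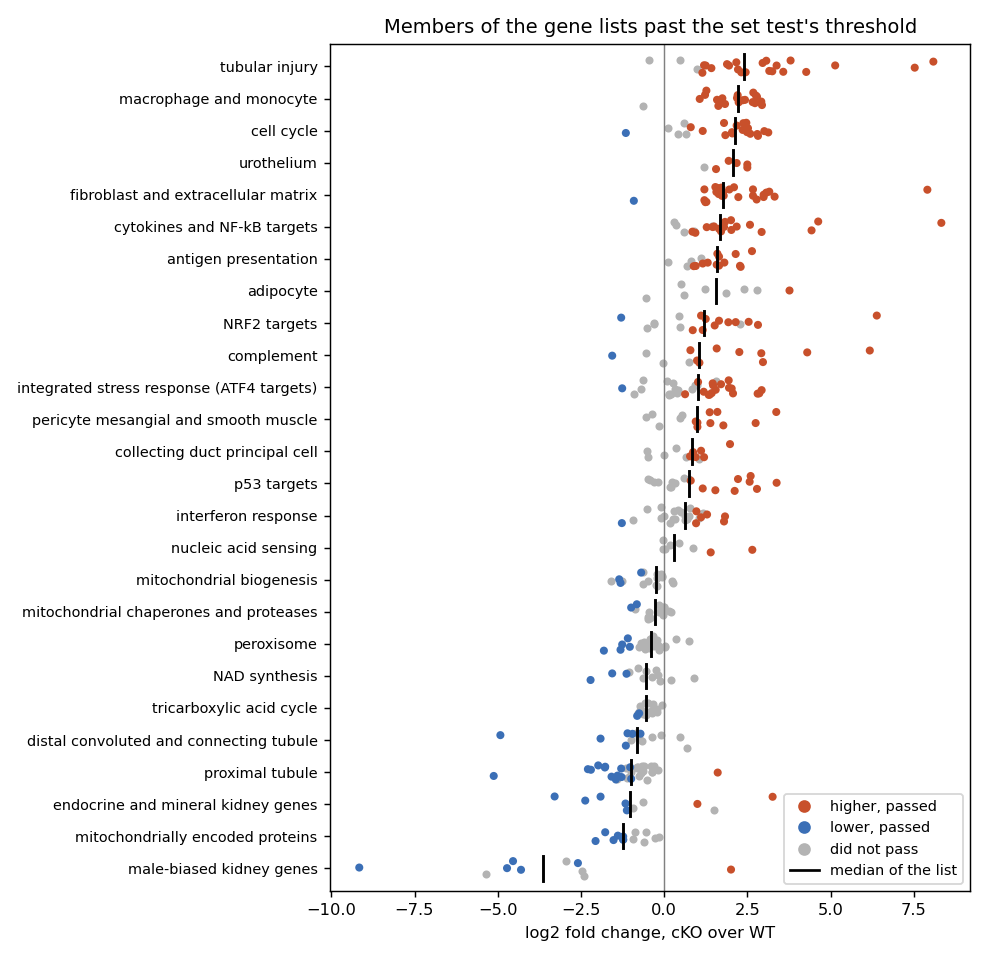
Log2 fold change (cKO over WT) of every tested member of the 26 gene lists past the camera threshold, 1 point per gene, coloured where the gene passed an adjusted p under 0.05, with a bar at each list's median. Injury, macrophage, matrix and cell cycle members lie mostly above 0, and members of the proximal tubule and distal tubule lists mostly below.

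Of the 13 proteins encoded by mitochondrial DNA, 7 had lower transcripts in cKO, 0 higher, with a median log2 fold change of -1.23 (camera adjusted p = 7e-05; adjusted p = 0.35 with an estimated correlation). The complex I subunit mt-Nd5 fell from 3458 ± 1528 to 1015 ± 211 CPM, a log2 fold change of -1.77 (SE 0.37, edgeR adjusted p = 0.00917), and lost its call, at -1.58, without WT 4 and cKO 4. There were 9 falls adjusted over the list alone and 3 with a sex term, and the median was -1.32 within the libraries without Y-linked reads and -0.96 within those with them. Mitochondrial genes took 9.23%, 4.51%, 9.05% and 8.26% of the counts in WT 1 to WT 4 and 4.1% to 5.05% in cKO. Nuclear genes of the respiratory chain were mostly not past the threshold. Of 16 complex IV subunits 1 rose, the isoform Cox6b2, from 3.57 ± 1.36 to 12.4 ± 2.35 CPM (camera adjusted p = 0.33). Among 21 complex IV assembly factors and 36 complex I subunits 1 each fell, the marginal Cox15 and Ndufs1 (camera adjusted p = 0.48 and 0.67). Of 28 subunits of complexes II, III and V and 77 mitochondrial ribosomal proteins 0 passed with edgeR (camera adjusted p = 0.44 and 0.63). In these 2 lists 1 and 4 had an unadjusted p under 0.05, 1 and 2 passed with DESeq2 and 0 and 1 with limma-voom. The medians of these 5 lists lay between -0.08 and 0.10. Without Y-linked reads they were -0.36, -0.22, -0.52, -0.47 and -0.14 in the order above, with them 0.18, 0.01, 0.08, 0.03 and 0.09, and with a sex term -0.11, -0.09, -0.23, -0.22 and -0.02. Those of the assembly factors, complex I and complexes II, III and V took the other sign when scaled by library size alone. Without WT 3 the camera adjusted p of complex I and of complexes II, III and V was 0.02, and without WT 2 that of the mitochondrial ribosomal proteins was 0.041. Adjusted over the list alone, and with a sex term, Cox6b2 passed and 0 of the other members of the 5 lists did.

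Mitochondrial biogenesis factors fell in 3 of 17 cases, median -0.23 (camera adjusted p = 0.0056; adjusted p = 0.26 with an estimated correlation), among them the coactivator Ppargc1a, from 41.0 ± 11.6 to 16.1 ± 6.45 CPM, with the marginal Esrrg and Polg. Mitochondrial chaperones and proteases fell in 2 of 16 cases, the marginal Hspd1 and Clpx, median -0.28 (camera adjusted p = 0.048; adjusted p = 0.35 with an estimated correlation). Without WT 1, WT 2, cKO 1 or cKO 4 the camera adjusted p of that list was 0.072, 0.12, 0.058 or 0.069, and with a sex term 0.077. When adjusted over the list alone 6 biogenesis factors and 3 chaperones or proteases fell, and with a sex term 0 did. These medians were -0.21 and -0.21 within the libraries without Y-linked reads and -0.50 and -0.26 within those with them. Hypoxia response genes went both ways, with 3 of 15 higher and 2 lower (camera adjusted p = 0.67), or 3 and 3 adjusted over the list alone. The carbonic anhydrase Car9 fell from 11.6 ± 4.55 to 0.932 ± 0.628 CPM and Vegfa from 83.7 ± 25.1 to 29.6 ± 6.68. Members that rose included Ndrg1 and the marginal Ankrd37. Of 18 endoplasmic reticulum chaperones 0 passed with edgeR or adjusted over the list alone (camera adjusted p = 0.93), with 2 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom. Autophagy and lysosome genes rose in 2 of 25 cases, the protease Ctsd and the marginal hydrolase Hexa, and in 1 adjusted over the list alone (camera adjusted p = 0.91). A sex term left 1 hypoxia gene higher and 2 lower, and 1 autophagy and lysosome gene higher. The medians of the hypoxia, chaperone and autophagy lists were 0.01, 0.30 and -0.03 without and -0.24, -0.15 and 0.06 with Y-linked reads.

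Tricarboxylic acid cycle genes were lower as a list, with 2 of 17 passing, the marginal Sucla2 and Idh2, and a median of -0.54 (camera adjusted p = 9.1e-05; adjusted p = 0.35 with an estimated correlation). Peroxisome genes fell in 5 of 24 cases, median -0.40 (camera adjusted p = 0.00089; adjusted p = 0.35 with an estimated correlation), including the D-aspartate oxidase Ddo, from 40.5 ± 2.97 to 16.2 ± 4.80 CPM, with Pecr, Crot and the marginal Agxt2 and Phyh. Genes of NAD synthesis fell in 3 of 13 cases, Afmid and the marginal Haao and Ido2, all in the route from tryptophan, median -0.53 (camera adjusted p = 0.0098; adjusted p = 0.45 with an estimated correlation; exact permutation p = 0.0571). Of these 3 lists, 4, 7 and 5 members fell adjusted over the list alone, and with a sex term 0, 2 and 0 did. Their medians were -0.46, -0.38 and -0.63 within the libraries without Y-linked reads and -0.35, -0.38 and -0.54 within those with them. Fatty acid oxidation genes passed in 3 of 24 cases, 2 lower and 1 higher. Acadm, a medium-chain acyl-CoA dehydrogenase, fell from 1389 ± 198 to 417 ± 104 CPM. The regulator Ppara also fell, a marginal call (camera adjusted p = 0.051, and 0.02, 0.036, 0.043 and 0.041 without WT 3, cKO 1, cKO 3 or cKO 4). In gluconeogenesis and ammoniagenesis Pck2 and Slc38a3 rose and Pcx, Slc37a4 and the marginal G6pc fell among 10 genes (camera adjusted p = 0.20). In cholesterol synthesis 3 of 20 genes rose, among them Fdps and the marginal Fdft1, and 2 fell, among them Cyp51, with a median of 0.10 (camera adjusted p = 0.68). In serine and one-carbon metabolism Mthfd2, Mthfd1l, Phgdh and Psat1 rose and 3 fell among 15, including the marginal Shmt2 and Mthfd1 (camera adjusted p = 0.66). In glycolysis the marginal Slc16a3, Pfkp and Hk2 rose among 17 (camera adjusted p = 0.55). In heme synthesis and breakdown 3 of 10 fell, the marginal Cpox, Fech and Uros, with a median of 0.07 but a mean of -0.18 and a downward test (camera adjusted p = 0.58). Adjusted over the list alone, the counts higher and lower were 1 and 2 for fatty acid oxidation, 2 and 4, 3 and 3, 4 and 4, and 3 and 1 for the next 4 lists, and 0 and 3 for heme. These counts were, with a sex term, 1 and 1, 2 and 0, 2 and 2, 1 and 0, 0 and 0, and 0 and 0. The medians of the 6 lists were -0.24, -0.39, 0.16, 0.09, -0.22 and 0.04 without and -0.26, -0.25, 0.38, 0.30, 0.39 and -0.12 with Y-linked reads, so those of glycolysis and heme differed in sign.

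Proximal tubule genes were lower in cKO, with 13 of 34 falling, 1 rising and a median log2 fold change of -1.01 (camera adjusted p = 8.6e-10; adjusted p = 0.35 with an estimated correlation). The organic anion transporter Slc22a7 (ENSMUSG00000067144, chromosome 17, 46432183 to 46438457) fell from 328 ± 38.7 to 9.33 ± 6.80 CPM, a log2 fold change of -5.12 (SE 0.45, edgeR adjusted p = 7.54e-05). The brush border peptidase Dpep1 fell from 184 ± 64.5 to 53.9 ± 15.4 CPM, and the sulfate transporter Slc13a1 rose from 278 ± 46.0 to 848 ± 264. Distal convoluted and connecting tubule genes fell in 6 of 14 cases, median -0.80 (camera adjusted p = 0.00088; adjusted p = 0.26 with an estimated correlation), with the calcium-binding protein Pvalb going from 44.9 ± 37.1 to 1.53 ± 0.909 CPM. Collecting duct principal cell genes rose in 6 of 12 cases, median 0.83 (camera adjusted p = 0.0046; adjusted p = 0.39 with an estimated correlation), and the water channel Aqp2 went from 282 ± 111 to 1111 ± 670 CPM. The call of Aqp2 ended with a sex term, with which its log2 fold change went from 1.98 (SE 0.44) to 1.71 (SE 0.48), and without WT 4 and cKO 4, at 1.2. When adjusted over the list alone 23 proximal and 9 distal tubule genes fell and 1 in each rose, and 7 collecting duct genes rose. With a sex term 2 proximal and 4 distal genes fell and 1 collecting duct gene rose, with medians of -0.73, -0.93 and 0.74. The medians of these 3 lists were -0.81, -0.92 and 0.60 within the libraries without Y-linked reads and -0.72, -0.85 and 0.78 within those with them.

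The other nephron lists did not pass. In the loop of Henle 1 of 13 genes rose, the tight junction gene Cldn16, and 2 fell, among them the marginal Ptger3 (camera adjusted p = 0.063, and 0.02, 0.021, 0.044, 0.043 and 0.046 without WT 3, WT 4, cKO 1, cKO 3 or cKO 4). With a sex term that list had a camera adjusted p of 0.0095. Among 13 intercalated cell genes the transcription factor Hmx2 rose and the anion exchanger Slc4a1 fell, both marginal (camera adjusted p = 0.28). Of 19 podocyte genes Nes rose and the marginal Tcf21 fell (camera adjusted p = 0.21), and of 9 nephron progenitor genes Wnt4 rose and the marginal Lhx1 fell (camera adjusted p = 0.93), a list whose median near 0 changed sign with the scaling. Endothelial genes passed in 4 of 18 cases. The VEGF receptor Kdr fell from 40.8 ± 4.81 to 18.6 ± 3.74 CPM, Ehd3 and the marginal Tek fell, and the marginal Eng rose (camera adjusted p = 0.13, and 0.027 without WT 4). In the loop of Henle 1 gene rose and 6 fell adjusted over the list alone, the counts of the intercalated, podocyte and progenitor lists stayed at 1 and 1, and 1 endothelial gene rose and 4 fell. The counts higher and lower with a sex term were 1 and 1, 0 and 0, 1 and 0, 1 and 0, and 0 and 1 for these 5 lists. In the order above, the medians of these 5 lists were -1.27, -0.51, -0.64, 0.18 and -0.47 within the libraries without Y-linked reads and -0.18, 0.01, 0.24, -0.01 and -0.10 within those with them.

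Kidney endocrine genes went both ways, with 5 of 10 lower and 2 higher and a median of -1.03 (camera adjusted p = 0.049; adjusted p = 0.43 with an estimated correlation; exact permutation p = 0.0571). Renin (Ren1) fell from 82.2 ± 38.1 to 8.34 ± 6.29 CPM and the angiotensin-converting enzyme Ace from 286 ± 102 to 55.3 ± 30.4. Klotho (Kl), a co-receptor for FGF23, fell from 573 ± 173 to 152 ± 79.5 CPM, and lost its call, at -1.67 on the log2 scale, without WT 4 and cKO 4. Cyp27b1, which activates vitamin D, rose from 1.86 ± 0.703 to 18.1 ± 7.84, as did Agt, while Agtr1a and Pth1r also fell. Without WT 1, WT 2, cKO 2 or cKO 4 the camera adjusted p of the list was 0.072, 0.076, 0.053 or 0.059, and with a sex term 0.098. Urothelial genes rose in 5 of 6 cases, median 2.06 (camera adjusted p = 7e-05; adjusted p = 0.26 with an estimated correlation), among them the basal keratin Krt5, from 2.87 ± 2.02 to 15.8 ± 5.47 CPM, with Krt14, Upk3a, Upk1b and the marginal Upk2. Of 8 adipocyte genes 1 rose, the marginal Retn, median 1.55 (camera adjusted p = 0.039; adjusted p = 0.63 with an estimated correlation; exact permutation p = 0.143), and without WT 1, WT 4, cKO 1 or cKO 2 the camera adjusted p was 0.059, 0.096, 0.12 or 0.062, and with a sex term 0.055. Its median was 2.81 within the libraries without Y-linked reads and -0.19 within those with them. The 4 tested globin genes fell, Hbb-bt and the marginal Hbb-bs, Hba-a1 and Hba-a2, with a median of -4.90, too few for a set test. With no count filter the red blood cell list had enough members, and it passed. Their total was 554, 242, 29.1 and 580 CPM in WT 1 to WT 4 and 8.73, 7.51, 27.8 and 3.07 in cKO 1 to cKO 4, so the lowest WT total lay close above the highest cKO total. The replicate block ended the calls of all 4, limma-voom called 2 and not Hbb-bt or Hba-a2, and reads shared within each globin pair leave the single genes uncertain. Adjusted over the list alone 7 endocrine genes fell and 3 rose, 6 urothelial genes and 1 adipocyte gene rose and 4 globins fell. With a sex term 4 endocrine genes fell and 2 rose, 2 urothelial genes and 0 adipocyte genes rose and 3 globins fell. The endocrine, urothelial and globin medians were -0.91, 2.11 and -6.36 within the libraries without Y-linked reads and -0.88, 1.51 and -3.44 within those with them.

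Lists of sex-biased kidney genes were compared in the same way. Male-biased genes fell in 5 of 10 cases and rose in 1, with a median of -3.63 (camera adjusted p = 0.013; adjusted p = 0.59 with an estimated correlation; exact permutation p = 0.143), but with a sex term the median was -1.21 and 2 fell. Those 2 were Kap and Slc22a30, the latter at -3.51 (edgeR adjusted p = 0.000151). Without the term, those that fell were Kap, Slco1a1, Slc22a30, Cyp7b1 and Cyp4b1 and the 1 that rose was Cyp4a12b, all marginal except Cyp4b1, one of the genes not run with a library left out. Within the libraries without Y-linked reads the median was 0.98, and within those with them -2.35. The androgen-dependent gene Kap had 43400, 69500, 38600 and 47300 CPM in WT 1 to WT 4 and 532, 754, 8660 and 124 in cKO 1 to cKO 4. Its log2 fold change of -4.30 (edgeR adjusted p = 0.034) passed, and without WT 2, WT 3, WT 4, cKO 1 or cKO 2 the edgeR adjusted p was 0.0577, 0.08, 0.0751, 0.0561 or 0.0881. With a sex term the log2 fold change of Kap was -4.55 (edgeR adjusted p = 0.00961). It was -6.53 within the libraries without Y-linked reads and -2.58 within those with them. The organic anion transporter Slco1a1 had 0 CPM in WT 1 and 617, 866 and 752 in the other WT libraries, against 0.244 to 1.37 in cKO, including 1.21 in cKO 3, which has Y-linked reads. Of 6 female-biased genes 1 rose, the marginal Gsta4, and 1 fell, Slc22a19 (camera adjusted p = 0.13, and 0.0008 without WT 1), with medians of -1.48 and 3.44 within the libraries without and with Y-linked reads. The cytochrome P450 gene Cyp4a14 had 688 CPM in WT 1 and 4.25 to 16.8 in the other WT libraries, against 1030 to 1710 in cKO. Of the Y-linked and Xist list 0 of 5 passed with edgeR, 0 with DESeq2 and 0 with limma-voom, and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.35, 0.0055 without WT 1 and 0.038 with a sex term). When adjusted over the list alone 7 male-biased genes fell and 1 rose, 1 female-biased gene rose and 1 fell, and 0 of the Y-linked and Xist genes passed.

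**Figure D4:**
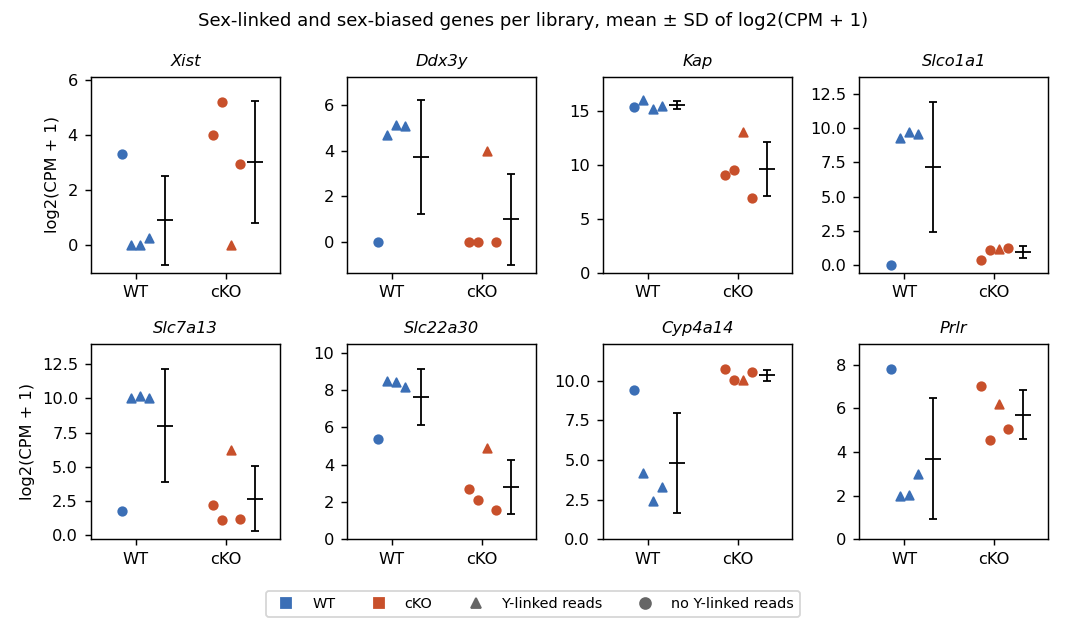
Normalised counts of 8 sex-linked or sex-biased genes as log2(CPM + 1), 1 point per library, with the mean and SD of each genotype beside the points (n = 4) and point shape giving the presence of Y-linked reads. Kap lies lower in all 4 cKO libraries, Slco1a1 lies near 0 in WT 1 and in all 4 cKO libraries, and Cyp4a14 lies at 1030 to 1710 CPM in cKO.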

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

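The tests of the sex imbalance on all called genes and of the proximal tubule share were chosen after the results were seen. In 31 of 346 groups of 4 libraries 1 library lay far from the other 3 (Dixon's test), where chance gives about 1 in 20, and 8 of the 31 were in WT 1 and 7 in cKO 2.

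In WT 1, CPM values stood apart for Spp1 (1950, against 446 to 557 in the other WT libraries), Jchain (36.4, against 1.26 to 5.04), Slc5a8 (111, against 417 to 466), Slc22a19 (331, against 142 to 170), Afmid (68.5, against 94.5 to 96.4), Mpeg1 (16.7, against 10.9 to 11.7), the marginal Ccdc170 (11.2, against 1.06 to 1.95) and Eif2s3y (0, against 40.6 to 46.2). In WT 2 they did for the marginal mt-Cytb (7380, against 12900 to 13900) and mt-Nd2 (2750, against 5410 to 5850) and Trib3 (1.84, against 0.949 to 0.98). Calr was at 770 in WT 3, against 635 to 650, and Tek and Cyp27b1 at 21.3 and 2.91 in WT 4, against 32.7 to 34.1 and 1.47 to 1.55. In cKO 1 Slc22a7 was at 19.4, against 4.46 to 6.85 in the other cKO libraries, and Ccdc170 at 0.366, against 0. In cKO 2 Jchain was at 32.7 (1.21 to 6.04 in the others), Mrpl28 at 238 (125 to 138), Pdia3 at 834 (563 to 600), H2-DMb1 at 94.8 (59.4 to 63.3), Ifi204 at 5.55 (3.48 to 3.7), Polg at 13.6 (21.7 to 22.8) and Tnn at 0 (0.061 to 0.0711). In cKO 3, the cKO library with Y-linked reads, Kap was at 8660 (124 to 754), Slc22a30 at 28.5 (2.02 to 5.49), Eif2s3y at 27.5 (0), Ddx3y at 14.9 (0), Hba-a1 at 6.69 (0.793 to 1.31) and Rhox6 at 0.142 (0). In cKO 4 Aqp2 was at 2110 (710 to 814) and Mthfd2 at 20.8 (9.9 to 11.7). The cKO values of Tnn and Rhox6 rest on very few counts, so their differences between libraries lie near the counting floor.

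A test of the interaction of genotype with sex passed for 9 genes, among them 2 taken by the naming rule, both marginal, and Cyp4a14, chosen after its values were seen. For Slco1a1 the fitted log2 fold change was 6.52 without and -9.26 with Y-linked reads, a difference of 15.77 (edgeR adjusted p = 0.0149). WT 1 held 0 counts of it, against 4, 10 and 21 in cKO 1, cKO 2 and cKO 4, so the fitted 6.52 and 15.77 depend on the prior count and do not measure a size. For Cyp7b1 the log2 fold changes were 1.25 and -4.42, a difference of 5.68 (edgeR adjusted p = 0.0288), and for Cyp4a14 1.035 and 6.718 (edgeR adjusted p = 0.0479). Each contrast rests on a single library on 1 side, WT 1 and cKO 3, so the test cannot separate sex from these libraries.

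The first pattern is the number of genes and lists that differed. Chance is argued against for the genes but not excluded: 1 of the 35 splits of the 8 libraries gave 2310 genes, the real one. That is the smallest share that 35 splits allow. The highest of the others gave 12, the split by Y-linked reads. Every other split mixes the genotypes, so its low count does not show what unrelated libraries would give. Chance cannot be excluded for the lists either, and is not argued against, since 7 of the 35 splits gave as many as the real 26 and the highest other gave 33. The other splits that reached 26 held unequal numbers of the genotypes and so kept part of the genotype difference. Those with equal numbers gave 3 to 18 lists. The splits thus do not decide on chance for the lists. The split by Y-linked reads gave 27 lists, and the fit of genotype with a sex term gave 25. The log2 folds of the 2310 genes had a median of 0.909 of their size with a sex term (quartiles 0.812 and 0.988). Each genotype holds both sexes, so a gene that follows sex alone varies within it and is seldom called. Ddx3y was at -2.61 with an edgeR adjusted p of 0.379. Picking called genes thus favours a ratio near 1, and the ratio does not decide on unequal sexes. With the term 931 of the 2310 were called. The median absolute log2 fold went from 1.49 to 1.32, the median SE from 0.33 to 0.37 and the residual degrees of freedom from 6 to 5, and their parts in the lost calls were not separated. The genotype remains untested against litter or age within sex, and for male-biased genes the part of sex stays open with 1 Y-bearing cKO library.

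The second pattern is the fall of proximal tubule genes. A smaller share of proximal tubule RNA and nothing else would raise the markers of all other cells alike, but the macrophage median lay 2.63 above the endothelial one (95% bootstrap interval 1.73 to 3.12, 39 genes), which argues against it as the whole cause. A lower share with more macrophages and nothing else would move the remaining cell types alike, but the fibroblast median lay 2.2 above the endothelial one (95% bootstrap interval 1.47 to 3.02, 44 genes), which argues against that too. Both intervals resample the genes of the lists and not the animals, so they do not cover the spread between kidneys. Tested across animals with edgeR, 20 of 21 macrophage genes rose and 0 fell, and 25 of 26 fibroblast genes rose and 1 fell. Of 18 endothelial genes 1 rose and 3 fell. Within the list Slc13a1 rose by 1.61 (SE 0.29) and Slc22a7 fell by 5.12 (SE 0.45). A lower share as part of the cause, beside changes in several cell types, stays open. The 14 called genes had a median of 0.946 of their log2 fold with a sex term (quartiles 0.789 and 1.02). They were picked by their call without that term, so this ratio does not decide on unequal sexes either. Of these 14, 3 stayed called with the term, where the median absolute log2 fold went from 1.59 to 1.27 at a median SE of 0.42 and 1 residual degree of freedom was lost. A change of expression within the cells that lost Cox10 may contribute and was not tested.

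The third pattern is Gm6300, an unprocessed pseudogene on chromosome 3 (14363117 to 14377587), chosen after its values were seen. It had 702, 1500, 1084 and 1219 counts in the WT libraries and 0 in each cKO library. A strain haplotype around the locus could give such a pattern, and 5 of the 23 other tested genes within 5 Mb were called (21.7%, against 16.7% elsewhere; odds ratio 1.39, 95% interval 0.402 to 3.88, Fisher's exact p = 0.572). With 23 genes the haplotype and an effect of genotype cannot be told apart.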

How the results depend on the processing

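The contrasts within each sex, the pair with the later sample numbers, the term for the number run and the permutation of list means were chosen after the data were seen, and the other alternatives before. Against 2310 genes, 1323 higher and 987 lower, a sex term gave 941 (715 and 226). Contrasts without and with Y-linked reads, each with a single library on 1 side, gave 120 (62 and 58) and 480 (413 and 67). There were 1397 genes, 426 lower, without the 2.5-month pair, and 568 (417 and 151) without WT 4 and cKO 4. An adjusted p under 0.01 gave 798 (589 and 209), and library size scaling 550 lower genes, with the median of all genes shifted by 0.159. Leaving out 1 library gave 1155 to 3093 genes, 815 to 1626 higher and 340 to 1467 lower, lowest without cKO 4 and highest without WT 1. Beyond 1.5 times also lay WT 3 (1438) and WT 4 (1288), and cKO 2 (586) for lower genes. The other alternatives stayed within 1.5 times, among them the replicate block at 2208, the number-run term at 1988, the age term at 2980 and DESeq2 at 3165. No called gene changed sign except in the contrasts without (32) and with (1) Y-linked reads. The cause of these moves was not tested.

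Cox10 passed the threshold in 0 of its 25 alternatives, at -0.29 to -0.01 with 1 library left out, -0.34 without WT 4 and cKO 4, and -0.48 and 0.07 within the libraries without and with Y-linked reads. Lists past the threshold numbered 3 with an estimated correlation and 25 to 30 with 1 library left out, 23 by fry and 25 with a sex term. Values near 0 that took the other sign were those of Mrpl12 (0.02 with library size scaling; -0.35 to 0.14 with 1 library left out), Mrpl28 (-0.03 with a sex term, -0.12 without Y-linked reads; -0.14 to 0.42), Pdia3 (-0.03 with Y-linked reads) and Jchain (0.07 with library size scaling; -1.52 to 1.72). Without Y-linked reads the called fall of Cpox (-1.15) was 0.00, Slco1a1 was 6.52, a fit against 0 counts, and Cyp7b1 1.25, each resting on WT 1 alone. DESeq2 ended the call of 0 of 171 named genes, and of the 172 RLE scaling ended that of 0, limma-voom of 9, a sex term of 57 and leaving out WT 4 and cKO 4 of 82. In data simulated at these depths with 4 libraries per group 18% of 2-fold changes were called, and depth was not varied. Far fewer genes were changed there than were called in the real data, so 18% is not the share for the real comparison.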

Other observations

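The gene families below were chosen after the data were seen, and the test of genes near Cox10 before. Some family members are also in the fixed lists, and no test of the families is given. Collagens rose in 19 of 30 cases and fell in 3, chemokines rose in 16 of 24 and fell in 1, and serpins rose in 13 of 23 and fell in 2. Keratins rose in 8 of 11 cases, matrix metalloproteinases in 8 of 11 and TNF receptor family members in 7 of 13. Tubulins rose in 7 of 16 cases and fell in 1. Solute carriers fell in 48 of 281 cases and rose in 18, and among those that fell were 9 of 20 Slc22 organic ion transporters. A sex term left 19 solute carriers lower, 6 of them of the Slc22 group, and 11 higher. The rises with that term numbered 16 for collagens, 14 for chemokines, 11 for serpins, 6 for keratins, 6 for matrix metalloproteinases, 5 for TNF receptors and 5 for tubulins, and of these families 1 serpin fell. Among other families, 5 of 31 Cyp2 and Cyp4 genes rose and 4 fell, and 5 of 14 Ugt genes rose and 4 fell. Of 33 potassium channels 2 rose and 7 fell. Of 96 cytosolic ribosomal proteins 3 rose and 0 fell, with a median log2 fold change of 1.01. With a sex term these counts higher and lower were 3 and 1, 5 and 0, 0 and 3, and 0 and 0.

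The following genes were chosen after their values were seen. The fibrinogen chains Fga, Fgb and Fgg rose from 16.5 ± 1.75, 1.04 ± 1.17 and 6.61 ± 3.32 to 254 ± 85.6, 45.6 ± 18.4 and 308 ± 146 CPM (SD, n = 4), each past the threshold also with a sex term. The phosphate transporter Slc34a2 rose from 3.54 ± 0.986 to 34.8 ± 5.64 CPM, and its proximal tubule relative Slc34a1 fell from 4140 ± 978 to 1515 ± 833, a call that ended with a sex term as the log2 fold change went from -1.45 (SE 0.43) to -1.14 (SE 0.45). Endothelin 1 (Edn1) rose from 1.13 ± 0.609 to 23.0 ± 1.79 CPM, and the myeloid receptor Trem2 from 0.247 ± 0.183 to 9.20 ± 3.24. Igfbp3 fell from 185 ± 25.4 to 16.3 ± 2.47 CPM and the sodium-proton exchanger Slc9a8 from 330 ± 56.7 to 28.7 ± 8.76. The mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 did not pass, at 621 ± 334 and 1125 ± 721 CPM in WT and 698 ± 240 and 1373 ± 519 in cKO. WT 1 held 1110 and 2160 CPM of them, against 389 to 574 and 607 to 1080 in the other WT libraries. The libraries are of polyadenylated RNA, and whether these counts follow the amount of ribosomal RNA was not tested.

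Passenger alleles carried with the floxed locus could change genes near Cox10. Of 259 tested genes within 10 Mb 38 were called (14.7%, against 16.7% elsewhere), an odds ratio of 0.855 with a 95% interval of 0.588 to 1.21 (Fisher's exact p = 0.402). The interval includes both a lower and a slightly higher share, so the test does not decide.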
